A study of Mus musculus with 59 samples.

How the data were processed

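The series holds 59 Affymetrix expression arrays of mouse tissue. Per the labels, the authors summarised and normalised them by robust multi-array averaging (RMA). The deposited values are RMA signal intensity on a linear scale, from 5.25 to 43115 over all probe sets and arrays. They were transformed to log2 here before anything else. In each tissue the arrays had nearly the same median intensity, from 34.7 to 36.8 in liver, from 72.6 to 76.1 in bone marrow and from 74.3 to 77.6 in spleen. The deposited intensity values of the 3 tissues therefore appear to have been normalized apart. Absolute levels in different tissues are set side by side only for genes that differ many-fold. This served to check the tissue names, to choose liver genes that are dim in spleen and to size the liver signal in spleen. No further normalization was applied. No 2 arrays were identical. The labels give no processing date or batch, so none could be tested.

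Of 45101 probe sets, 64 are controls and were left out of the tests. The platform annotation gives exactly 1 gene symbol for 34945 of the others, several for 932 and none for 9160, and the last 2 kinds were left out. The gene identifiers of 34754 of the probe sets with 1 symbol were found in the RefSeq annotation of assembly GRCm38.p6, and 0 symbols had to be updated. These probe sets stand for 18193 genes, of which 9010 have several. In each tissue the probe set with the highest mean over that tissue's samples stood for its gene. Genes whose mean lay at or above the 40th percentile of all genes in that tissue were tested, which left 10916 genes per tissue. The lowest mean intensity that passed this filter was 42.9 in liver, 83.6 in bone marrow and 79.5 in spleen.

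Each tissue was fitted with limma (lmFit and eBayes) on the log2 values of its 4 groups, which share 1 estimate of spread per gene. The contrasts were baclofen minus vehicle at each time, the change of that difference from 1 to 5 days, and vehicle at 5 days minus vehicle at 1 day. Differences of the baclofen effect between tissues came from a fit of all 12 groups, on genes that passed the brightness filter in both tissues. Here the probe set with the highest mean over all samples stood for the gene. A gene passed the test when its 2-sided p, adjusted by the method of Benjamini and Hochberg over the genes tested in that comparison, was under 0.05. Fold changes are given on the log2 scale with limma's standard error (SE). The p-values measure only the spread between samples, because the labels number the replicates without saying outright that each is a separate animal. Groups of the 1-day livers follow the sample titles and the treatment field.

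Before the data were examined, 46 gene lists with 677 genes were fixed, covering pathways of liver and blood cells and markers of the cell types the tissues could hold. Some genes stand in several lists, so the calls of those lists are not independent of each other. A probe set was found for 608 of these genes, and the other 69 have no value here. Lists with at least 4 tested members were tested with camera at a preset correlation of 0.01 between genes, with p adjusted over lists and over the 6 baclofen comparisons. An estimated correlation was used in its place as an alternative. The function fry, which asks whether a list's genes move one way on balance and compares them with no other genes, was the other alternative. Members past the threshold were counted with p adjusted over all genes tested and adjusted over the list alone. The genes named were chosen from a set selected by rule, and not all genes of the set are named. It holds the 12 largest rises and the 12 largest falls past the threshold in each baclofen comparison. It also holds up to 4 members of each list with the smallest adjusted p, and the receptor subunit gene Gabbr1. Where no member of a list passed, it holds up to 2 members with the largest differences. In the other comparisons up to 5 rises and 5 falls are named. Symbols that are only clone or predicted-gene identifiers are counted and not named. The genes that passed in all 6 baclofen comparisons, and Cirbp, were added after the data were seen.

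The alternatives fixed before the data were examined were no brightness filter, a filter at the 60th percentile, the mean of a gene's probe sets, all probe sets apart, quantile normalization, centring of each array on its median, eBayes with trend and robust options, a fit of only the groups compared, array weights, the difference between 3' and 5' control probe sets as a covariate, adjusted p under 0.01, a minimum of 1.5-fold change, the replicate number as a block, the source field as the label of the 1-day livers, and each replicate left out in turn. An added alternative, chosen after seeing the data, leaves out 4 libraries that hold transcripts of another tissue. Of 367 calls of genes selected by the naming rule, 160 concern genes with several probe sets, and 0 of these have a probe set called in the other direction. Group means of a list over samples were compared by exact permutation tests, 2-sided.

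The pipeline was tested on simulated values with known changes before the counts were made, and the values given here are from a later repeat with another random seed. In the simulated comparison of 3 with 4 livers it recovered 70.2% of genes changed by 0.5, 86.6% of genes changed by 1 and 98.3% of genes changed by 2 on the log2 scale, 0 with the wrong sign, and 7 of its 171 calls were false. Some other comparisons did less well. For the change from 1 to 5 days in liver 40.3% of genes changed by 0.5 were recovered. In the simulated differences between tissues, 23 of 182 calls were false for liver and spleen at 1 day, where 2 genes passed before any change was added, and 18 of 177 for liver and bone marrow at 5 days. In the simulated spleen, where the T cell list was shifted by 0.5, camera called that list and 0 others of the 40 tested, with either kind of correlation, and fry called it and 1 other. The simulated probe sets were drawn independently of each other, so this does not show how the list tests do where genes move together. The work was done in R 4.3.3 with limma 3.58.1, and figures were drawn with matplotlib 3.10.9.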

Results

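Liver, bone marrow from the right humerus and spleen were taken from B6C3F1 mice given baclofen or vehicle by daily dosing. Baclofen, a muscle relaxant, is an agonist of the GABA-B receptor. The vehicle was 0.5% methylcellulose. Mice received 1 or 5 daily doses, and tissues were collected 2 h after the last one. The labels do not give the dose. RNA was hybridised to 59 whole-genome arrays. Liver had 3 vehicle and 4 baclofen arrays at 1 day and 4 vehicle and 8 baclofen arrays at 5 days. Bone marrow and spleen each had 4 vehicle and 4 baclofen arrays at 1 day and 4 and 8 at 5 days. An array gives an intensity with no count behind it, so the number of arrays limits the precision. Each comparison asks which transcripts differed between baclofen and vehicle after 1 or 5 doses. The change from 1 to 5 days and the differences between tissues have their own tests.

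Marker genes matched the tissue names. The mean log2 intensity of 12 hepatocyte genes was 14.38 ± 0.03 (SD, n = 19) in liver and 5.21 ± 0.10 (n = 20) in bone marrow. The mean of 13 mature neutrophil genes was 13.25 ± 0.14 (n = 20) in bone marrow and 4.83 ± 0.21 (n = 19) in liver. Correlation over probe sets was at least 0.970 between arrays of 1 tissue and at most 0.958 between arrays of different tissues. These are correlations across genes, which are not independent replicates. A few libraries held transcripts of another tissue. In spleen the hepatocyte mean was 9.17 in vehicle 5 day replicate 3, 9.05 in baclofen 5 day replicate 5 and 6.74 in vehicle 5 day replicate 1, against 4.78 to 5.86 in the other 17. In bone marrow the skeletal muscle mean was 9.68 in baclofen 1 day replicate 3, against 6.44 to 7.86 in the other 19. For 5 of the 7 livers at 1 day the source field names another treatment than the title. The title and the treatment field name the same treatment and were used. Under the labels of the source field 0 genes passed the test in liver at 1 day, and all 38 of the genes followed through the alternatives that passed there changed sign.

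**Figure D1:**
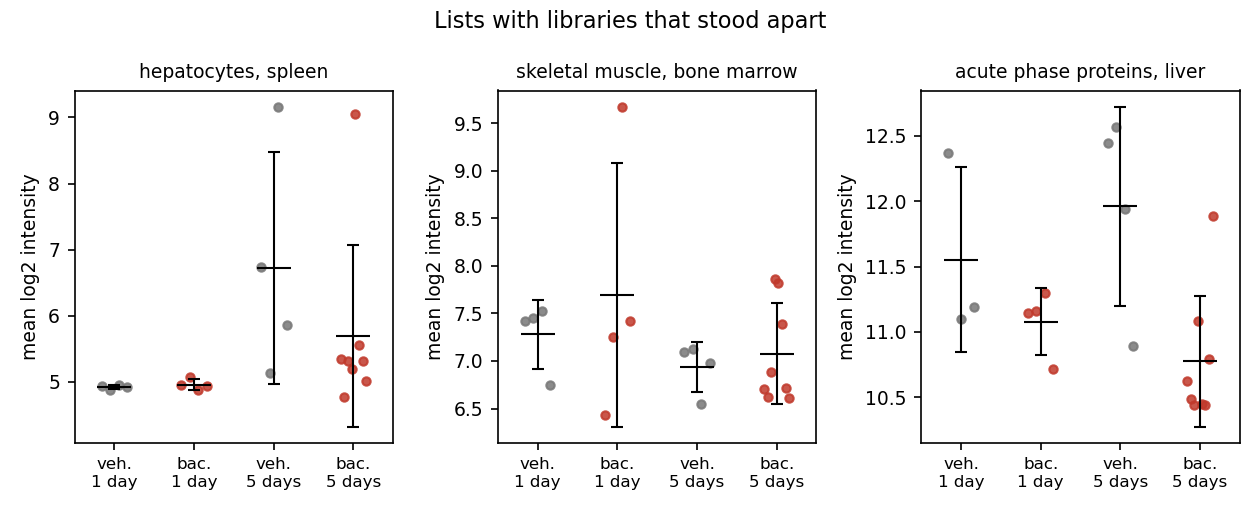
Mean log2 intensity of hepatocyte genes in spleen, skeletal muscle genes in bone marrow and acute phase genes in liver, 1 point per library, with black bars for the group mean ± SD. The 3 spleen libraries with hepatocyte transcripts and the marrow library with muscle transcripts stand above the rest.

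After 1 dose, the liver showed a rise of genes of glucose output and hormone response. Igfbp1, an insulin-repressed binding protein for insulin-like growth factors (NCBI Gene 16006, GRCm38.p6 chromosome 11, 7197787 to 7202546), rose 19.8-fold, by 4.31 ± 0.60 on the log2 scale (SE, 3 vehicle and 4 baclofen, adjusted p = 0.000349). Ddit4, an inhibitor of mTORC1 signalling (NCBI Gene 74747, chromosome 10, 59949675 to 59951770), rose 10.8-fold, by 3.43 ± 0.45 (adjusted p = 0.000262). Trp53inp1 rose by 2.50 ± 0.22 (adjusted p = 5.39e-06), and Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, by 3.11 ± 0.49. The lipid transporter gene Mfsd2a rose by 3.06 ± 0.39, the lipid droplet gene Plin4 by 2.76 ± 0.39, Snhg3 by 3.23 ± 0.45 and Fam107a by 2.58 ± 0.49. Phlda1 fell 7.11-fold, by 2.83 ± 0.38 on the log2 scale, and Osgin1 fell by 2.19 ± 0.30. Genes of 3 hepatocyte transcription factors fell, Hhex by 2.58 ± 0.50, Foxq1 by 2.12 ± 0.41 and Foxa1 by 1.93 ± 0.32. So did the Wnt receptor gene Fzd7 by 1.80 ± 0.33 and the inhibitors of basic helix-loop-helix factors Id2 by 1.80 ± 0.34 and Id3 by 1.54 ± 0.29.

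Of 17 tested glucocorticoid response genes in liver at 1 day, 10 rose, 0 fell and 7 did not pass, and 14 rose when adjusted over the list alone. Sgk1 rose by 1.89 ± 0.31, Dusp1, a MAP kinase phosphatase, by 2.10 ± 0.40, and Tat, tyrosine aminotransferase, by 1.39 ± 0.22. Of 11 gluconeogenesis and insulin-repressed genes 7 rose and 0 fell, 8 when adjusted over the list alone. G6pc, the catalytic subunit of glucose-6-phosphatase, rose by 1.75 ± 0.23, Ppargc1a by 1.57 ± 0.24 and Foxo1 by 1.04 ± 0.13. Camera called both lists (adjusted p = 9.24e-18 and 5.71e-14), and both held with an estimated correlation (adjusted p = 0.00131 for each). Of 12 urea cycle and amino acid breakdown genes 4 rose, also when adjusted over the list alone, among them Ass1 by 2.36 ± 0.36 and Gpt2 by 0.68 ± 0.12 (camera adjusted p = 1.23e-05, adjusted p = 0.604 with an estimated correlation). Of 9 cAMP and CREB response genes 4 rose, 5 when adjusted over the list alone (camera adjusted p = 0.00048, adjusted p = 0.108 with an estimated correlation). The 4 are Ppargc1a, Dusp1, Per1 and Sik1. Dusp1 and Per1 are also in the glucocorticoid list, and Ppargc1a is also in the gluconeogenesis list. Tat, Gpt2 and Got1, which rose beside Ass1 in the urea cycle list, are in the gluconeogenesis list too. These calls are therefore not separate from those of the lists above. The cold-inducible RNA-binding protein gene Cirbp (NCBI Gene 12696, chromosome 10, 80165990 to 80172786) rose by 1.92 ± 0.30. Herpud1 of the unfolded protein response rose by 0.92 ± 0.16 and the glucose transporter gene Slc2a1 by 0.93 ± 0.14. In contrast, of 18 acute phase genes only Socs3 fell, by 1.10 ± 0.29, and the list's median log2 fold change was -0.36. Camera called it (adjusted p = 0.00643, adjusted p = 0.845 with an estimated correlation), and without vehicle replicate 1 the adjusted p was 0.518. Of the 37 lists tested as sets, 23 had no member past the threshold, among them cholesterol synthesis, ribosomal proteins and heat shock proteins.

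In all, 291 of 10916 genes passed in liver at 1 day, 172 up and 119 down (limma). The count was 181 without vehicle replicate 1, 136 without vehicle replicate 2 and 184 without baclofen replicate 4, and 518 with array weights. Per1, which rose by 1.77 ± 0.37, lost its call without vehicle replicate 1 (adjusted p = 0.0884), and the metallothionein gene Mt2, which rose by 3.26 ± 0.76, lost it without vehicle replicate 2 (adjusted p = 0.0994) and without 4 other libraries in turn. Socs3 lost its call without any 1 of 6 of the 7 libraries, with the highest adjusted p, 0.232, without vehicle replicate 1.

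**Figure D2:**
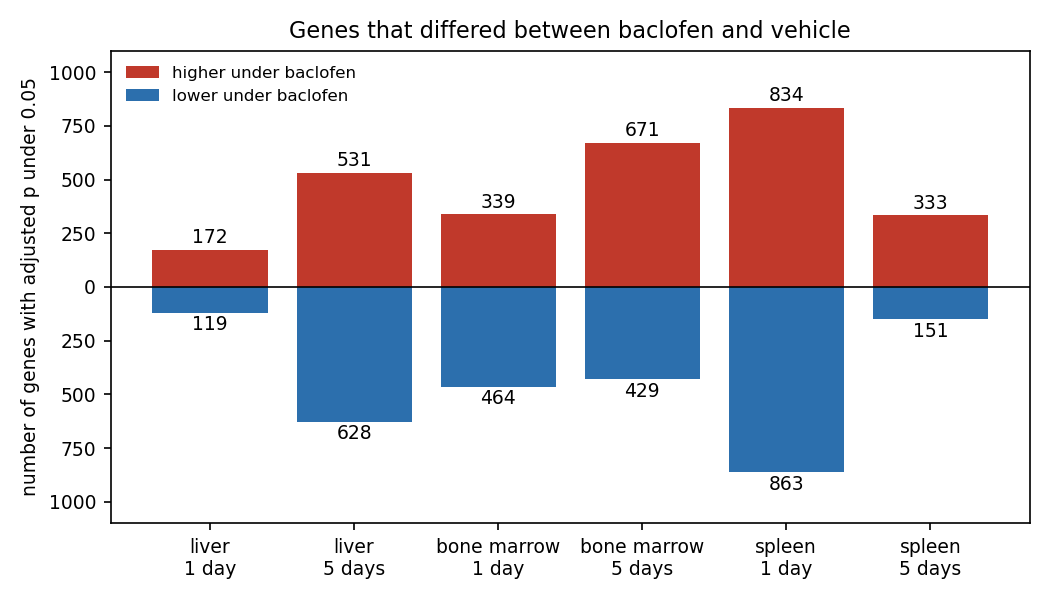
Number of genes with an adjusted p under 0.05 that were higher (red, above 0) or lower (blue, below 0) under baclofen than under vehicle in each tissue and time. Spleen at 1 day had the most, 834 up and 863 down.

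After 5 doses, the liver showed the rises of glucose output genes again, along with a fall of 8 of 18 acute phase genes. Ppp1r3g rose 15.9-fold, by 3.99 ± 0.39 (SE, 4 vehicle and 8 baclofen, adjusted p = 7.2e-06), and Igfbp1 rose 9.57-fold, by 3.26 ± 0.48 (adjusted p = 0.000402). Mfsd2a rose by 2.47 ± 0.31, Rasgef1b by 2.41 ± 0.22, Noct, a clock-controlled gene, by 2.29 ± 0.44, Fam107a by 2.20 ± 0.40, Lpin1, a phosphatidate phosphatase, by 1.97 ± 0.41 and Plk3 by 1.97 ± 0.30. The acute phase genes Lcn2 and Saa3 had log2 fold changes of -3.80 ± 0.93 and -3.09 ± 0.82. Id3 fell by 2.12 ± 0.23 (adjusted p = 1.71e-05), Id2 by 2.02 ± 0.27, the transcription factor gene Tbx3 by 1.75 ± 0.17 (adjusted p = 5.86e-06), the nuclear RNA Neat1 by 1.77 ± 0.24, and Angptl8, an insulin-induced hepatokine, by 2.26 ± 0.34.

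The glucocorticoid response list of liver at 5 days had 12 of 17 members up, 1 down and 4 not past the threshold, and 13 up and 1 down when adjusted over the list alone. Per1, a clock gene (NCBI Gene 18626, chromosome 11, 69095108 to 69109965), rose by 1.86 ± 0.30 and Tat by 1.35 ± 0.18. Of 11 gluconeogenesis and insulin-repressed genes 8 rose by either adjustment. Pck1, phosphoenolpyruvate carboxykinase, rose by 0.90 ± 0.10, Ppargc1a by 1.71 ± 0.19 and Foxo1 by 1.09 ± 0.10. Both lists were called by camera (adjusted p = 4.23e-10 and 8.05e-11) and held with an estimated correlation (adjusted p = 0.015 and 0.00238). Of 12 urea cycle and amino acid breakdown genes 8 rose by either adjustment, among them Got1 by 1.16 ± 0.17 and Arg1 by 0.37 ± 0.07 (camera adjusted p = 9.64e-08, adjusted p = 0.399 with an estimated correlation). Of 13 xenobiotic metabolism genes 4 rose and 0 fell, 5 when adjusted over the list alone, among them Cyp2b10 by 1.96 ± 0.47 and Cyp2c29 by 0.25 ± 0.05 (camera adjusted p = 0.00048, adjusted p = 0.536 with an estimated correlation). Cyp2b10 lost its call without vehicle replicate 2 or 3 (adjusted p = 0.0555 and 0.0666). Of 15 clock genes 4 rose, with Ciart up by 2.02 ± 0.40 and Nr1d2 by 0.80 ± 0.18, and 6 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.00503, adjusted p = 0.644 with an estimated correlation). Of 14 hypoxia response genes 4 rose, 7 up and 1 down when adjusted over the list alone, with Pfkfb3, an enzyme that sets the level of a glycolysis activator, up by 1.60 ± 0.25 (camera adjusted p = 0.0264, adjusted p = 0.338 with an estimated correlation). That list call was lost in 4 of the other settings, such as no brightness filter. Of 16 unfolded protein response genes 1 rose and 3 fell, Manf by 0.77 ± 0.23 among them, and camera did not call the list (adjusted p = 0.119). Manf lost its call without vehicle replicate 2 (adjusted p = 0.148) and without 5 other libraries in turn.

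Of 18 acute phase genes in liver at 5 days, 8 fell and 0 rose, and 15 fell when adjusted over the list alone (camera adjusted p = 1.97e-07, adjusted p = 0.695 with an estimated correlation). The list's mean ranged from 10.9 to 12.6 in the 4 vehicle livers and from 10.4 to 11.9 in the 8 baclofen livers (exact permutation p = 0.00808). Lcn2 lost its call without vehicle replicate 2 (adjusted p = 0.0618), and Saa3 without vehicle replicate 1 or 2 (adjusted p = 0.0671 and 0.0975). The macrophage gene Mpeg1 fell by 0.77 ± 0.19, and Prtn3, a gene of granulocyte precursors, by 1.31 ± 0.31, and 2 of 15 monocyte and macrophage genes fell in all. Mpeg1 lost its call without vehicle replicate 2 (adjusted p = 0.0738) and Prtn3 without vehicle replicate 3 (adjusted p = 0.0595). A sign of RNA quality, the difference between 3' and 5' control probe sets, was 0.50 ± 0.06 (SD, n = 4) in vehicle and 0.44 ± 0.04 (n = 8) in baclofen livers at 5 days.

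In all, 1159 of 10916 genes passed in liver at 5 days, 531 up and 628 down (limma). The count was 710 without vehicle replicate 2, 584 without vehicle replicate 3, 739 with the RNA quality sign as a covariate and 720 with array weights. At both times 105 genes rose, against 8.37 expected if the calls were independent, 50 fell, against 6.85 expected, and 0 moved in opposite directions. The log2 fold changes at 1 and 5 days correlated with r = 0.59 and rho = 0.36 across genes.

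The change of the baclofen effect from 1 to 5 days in liver passed for 2 genes by limma, with 1050 at an unadjusted p under 0.05. The effect at 5 days minus that at 1 day was -0.93 ± 0.15 for Ccn1, a secreted matrix protein gene, and -0.87 ± 0.14 for the Wnt receptor gene Fzd5 (adjusted p = 0.0279 for each). Ccn1 stood at 5.90 in vehicle and 6.06 in baclofen livers at 1 day and at 6.63 and 5.87 at 5 days. Fzd5 stood at 6.79 and 6.86 at 1 day and at 6.81 and 6.01 at 5 days. The count was 0 without vehicle 1 day replicate 1, baclofen 1 day replicates 1, 2 or 4, vehicle 5 day replicates 1 or 3 or baclofen 5 day replicates 1, 5, 6 or 7, 1 without vehicle 1 day replicate 2, 4 without vehicle 1 day replicate 3 and 6 without vehicle 5 day replicate 4.

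After 1 dose, bone marrow showed its largest rises in Cirbp, Ddit4 and Per1. Cirbp rose 5.33-fold, by 2.41 ± 0.25 (SE, 4 vehicle and 4 baclofen, adjusted p = 3.74e-05). Ddit4 rose 4.94-fold, by 2.30 ± 0.31, and Per1 rose 4.40-fold, by 2.14 ± 0.22 (adjusted p = 3.74e-05). Pik3ip1, an inhibitor of PI3-kinase, rose by 1.36 ± 0.18, Klf9 by 1.23 ± 0.22 and Arrdc3 by 1.07 ± 0.16. Ifit1bl2 fell 2.96-fold, by 1.57 ± 0.20, Bex6 by 1.00 ± 0.17 and Thap2 by 0.97 ± 0.15. Hk2, a hexokinase, fell by 0.84 ± 0.18, Hnmt, histamine N-methyltransferase, by 0.83 ± 0.19, the transcription factor gene Klf4 by 0.83 ± 0.14, and Ltb, lymphotoxin beta, by 0.82 ± 0.13.

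Of 15 glucocorticoid response genes in bone marrow at 1 day, 9 rose, 0 fell and 6 did not pass, and 13 rose when adjusted over the list alone. Dusp1 rose by 1.69 ± 0.21 and Nfkbia, an inhibitor of NF-kB, by 0.50 ± 0.07 (camera adjusted p = 6.88e-13, adjusted p = 0.123 with an estimated correlation). Of 11 cAMP and CREB response genes 4 rose by either adjustment, the immediate early gene Fos by 0.95 ± 0.17 (camera adjusted p = 0.00249, adjusted p = 0.108 with an estimated correlation). Per1 and Dusp1, which are also glucocorticoid response genes, are among the 4. Of 14 immediate early genes 2 rose and 2 fell, 3 up and 6 down when adjusted over the list alone, and camera did not call the list. Its median log2 fold change was -0.20 and its mean 0.03, so the middle and the average differ in sign. Vegfa, a growth factor of blood vessels, fell by 0.45 ± 0.11, and lost its call without baclofen replicate 1 (adjusted p = 0.0653). The heat shock co-chaperone gene Chordc1 fell by 0.51 ± 0.09 and was the only heat shock gene of 13 past the threshold. The erythroid list had 0 of 23 members past the threshold and a median of 0.15 (camera adjusted p = 0.0161, adjusted p = 0.847 with an estimated correlation), and that call was lost without vehicle replicate 2 (adjusted p = 0.156), vehicle replicate 4 or baclofen replicate 1 or 4. Acp5, a gene of bone-resorbing osteoclasts, rose by 0.91 ± 0.22 and lost its call without baclofen replicate 1 (adjusted p = 0.0563). In baclofen replicate 3, the library with muscle transcripts, 10 of 10 muscle genes had their highest marrow value, and of the 8 muscle genes tested 0 passed.

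In all, 803 of 10916 genes passed in bone marrow at 1 day, 339 up and 464 down (limma). The count was 303 without baclofen replicate 1, 423 without baclofen replicate 2, 349 without baclofen replicate 4, 369 without vehicle replicate 3, 533 without vehicle replicate 4 and 1412 without baclofen replicate 3, the library with muscle transcripts. A fit of only these 8 arrays gave 269 and array weights gave 2416.

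After 5 doses, Ddit4 and Per1 had the largest rises in bone marrow, and genes of red cells rose together. Ddit4 rose 5.09-fold, by 2.35 ± 0.27 (SE, 4 vehicle and 8 baclofen, adjusted p = 9.79e-05), and Per1 rose 4.66-fold, by 2.22 ± 0.19 (adjusted p = 1.96e-06). Cirbp rose by 1.34 ± 0.22, Dusp1 by 1.22 ± 0.19, Pik3ip1 by 1.19 ± 0.16, Klf9 by 1.14 ± 0.19, Zbtb16 by 1.05 ± 0.18, Tsc22d3, the glucocorticoid-induced leucine zipper, by 0.98 ± 0.13 and Rnase2a by 0.97 ± 0.18. Ifit1bl2 fell by 1.20 ± 0.17, Upp1, uridine phosphorylase, by 1.14 ± 0.19, the myeloid receptor gene Clec5a by 0.88 ± 0.15 and Lrg1 by 0.85 ± 0.19.

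Of 23 erythroid genes in bone marrow at 5 days, 18 rose and 0 fell, and 21 rose when adjusted over the list alone (camera adjusted p = 1.27e-13, adjusted p = 0.536 with an estimated correlation). Epor, the erythropoietin receptor, rose by 0.53 ± 0.10, Tspan33 by 0.52 ± 0.10 and Fech, ferrochelatase of haem synthesis, by 0.48 ± 0.10. The list's mean was 11.75 ± 0.24 (SD, n = 4) in vehicle and 12.13 ± 0.12 (n = 8) in baclofen marrow (exact permutation p = 0.00404). Vehicle replicate 1 had the lowest mean, 11.39, and without it Fech lost its call (adjusted p = 0.0565). The RNA quality sign was 0.04 ± 0.01 (SD, n = 4) in vehicle and 0.09 ± 0.05 (n = 8) in baclofen marrow at 5 days, and with it as a covariate 801 genes passed. Of 7 granulocyte precursor genes 1 fell, Prtn3 by 0.46 ± 0.13, and all 7 fell when adjusted over the list alone (camera adjusted p = 0.000547, adjusted p = 0.808 with an estimated correlation). Of 13 mature neutrophil genes 2 fell, Cd177 by 0.38 ± 0.12 among them, and 6 when adjusted over the list alone (camera adjusted p = 0.000708, adjusted p = 0.845 with an estimated correlation). Without vehicle replicate 1 Cd177 and Prtn3 lost their calls (adjusted p = 0.192 and 0.121), and without 7 and 3 other libraries in turn they lost them too. Of 20 DNA replication genes 3 rose, 6 when adjusted over the list alone, Tk1, thymidine kinase, by 0.35 ± 0.08 (camera adjusted p = 7.13e-05, adjusted p = 0.845 with an estimated correlation).

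The glucocorticoid response list of marrow at 5 days had 11 of 15 members up and 1 down by either adjustment (camera adjusted p = 4.22e-09, adjusted p = 0.293 with an estimated correlation). Of 15 unfolded protein response genes 6 fell, 9 when adjusted over the list alone, Xbp1 by 0.32 ± 0.07 among them (camera adjusted p = 0.00368, adjusted p = 0.674 with an estimated correlation). Of 13 heat shock genes 4 fell by either adjustment, Hspa1b by 0.76 ± 0.16 and Chordc1 by 0.37 ± 0.07 (camera adjusted p = 0.00103, adjusted p = 0.841 with an estimated correlation). Of 16 hypoxia response genes 1 rose and 3 fell, 1 up and 7 down when adjusted over the list alone. Among these, the mitochondrial kinase gene Pdk1 rose by 0.38 ± 0.06 and Vegfa fell by 0.45 ± 0.09 (camera adjusted p = 0.0236, adjusted p = 0.845 with an estimated correlation). Without vehicle replicate 1 the list's adjusted p was 0.103, and with the filter at the 60th percentile it was 0.223. Of 17 interferon response genes 3 fell, 4 when adjusted over the list alone, and the camera call (adjusted p = 0.0176, adjusted p = 0.845 with an estimated correlation) was lost without vehicle replicate 2 (adjusted p = 0.292). The macrophage adhesion gene Vcam1 rose by 0.43 ± 0.09 and the elastase gene Cela1 by 0.56 ± 0.10.

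In all, 1100 of 10916 genes passed in bone marrow at 5 days, 671 up and 429 down (limma). The count was 244 without vehicle replicate 1, 434 without vehicle replicate 3, 688, 634, 652 and 620 without baclofen replicates 1, 2, 5 and 6, and 1674 without baclofen replicate 8. Array weights gave 4404. At both times, 161 genes rose, against 20.8 expected, 158 fell, against 18.2 expected, and 0 moved in opposite directions (r = 0.69 and rho = 0.66 across genes). The change of the effect from 1 to 5 days passed for 0 genes by limma, with 559 at an unadjusted p under 0.05, and for 1 gene without baclofen 5 day replicate 7.

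**Figure D3:**
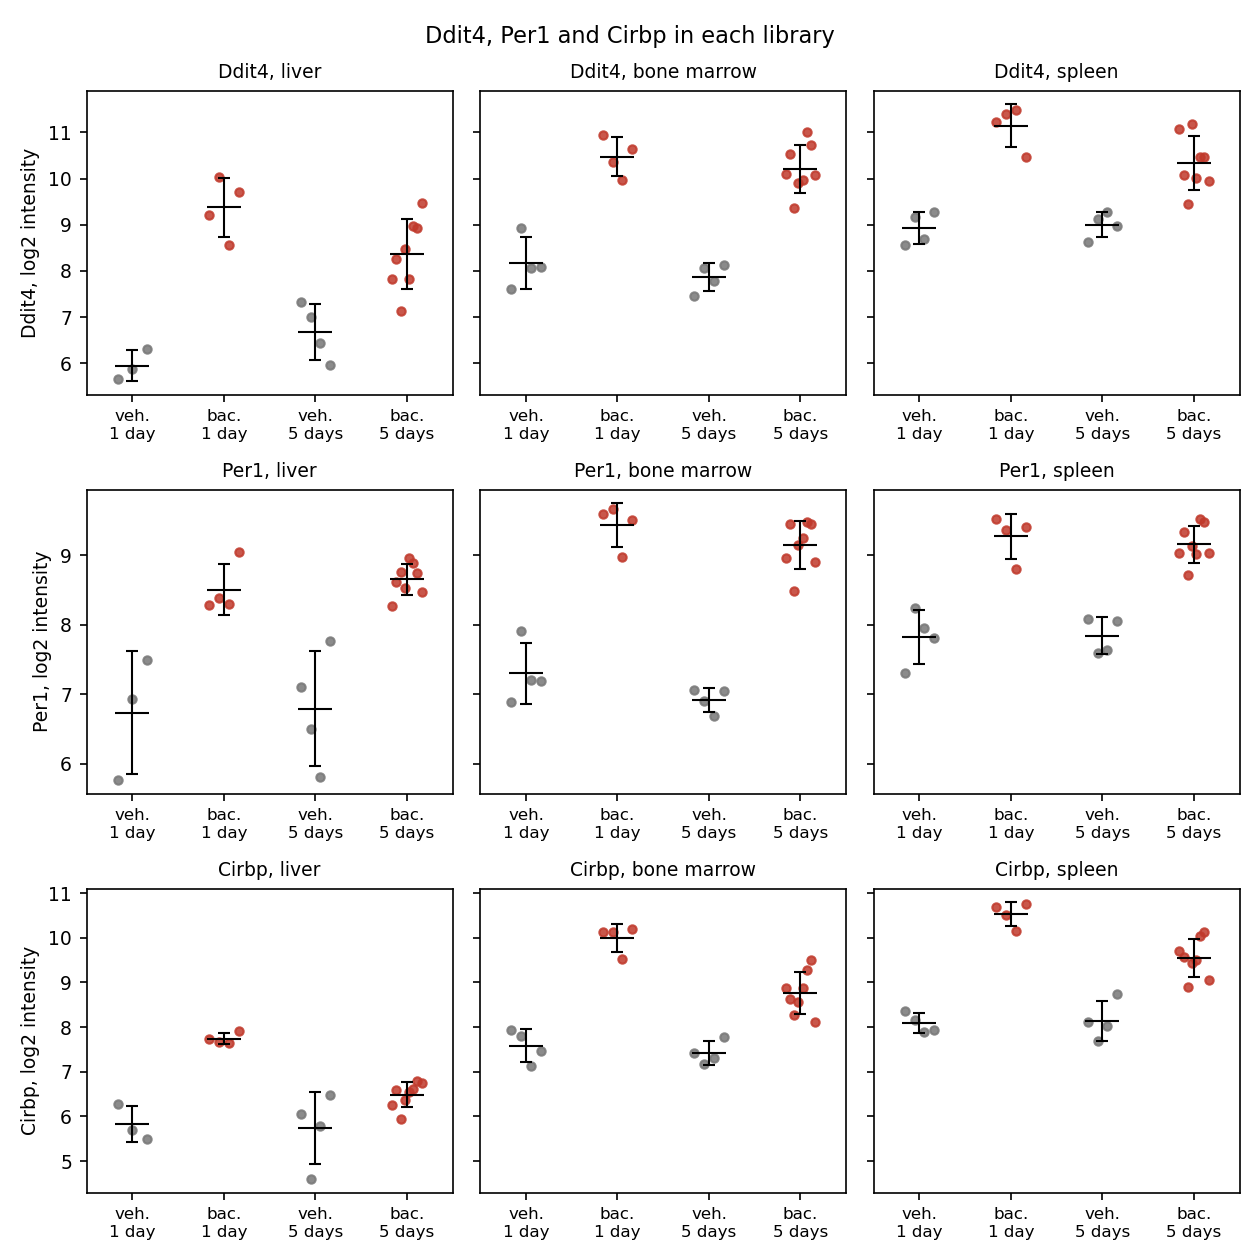
Log2 intensity of Ddit4, Per1 and Cirbp in each library of each tissue, with black bars for the group mean ± SD. In each tissue and at each time the mean of each gene was higher under baclofen, and each difference passed the test except that of Cirbp in liver at 5 days.

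After 1 dose, the spleen showed its largest rises in Cirbp, Ddit4 and Errfi1. Cirbp rose 5.43-fold, by 2.44 ± 0.24 (SE, 4 vehicle and 4 baclofen, adjusted p = 5.42e-05). Ddit4 rose by 2.22 ± 0.31, Errfi1, a feedback inhibitor of the EGF receptor, by 2.13 ± 0.28, and Pdk4, a pyruvate dehydrogenase kinase, by 2.01 ± 0.36. Fam107a rose by 1.97 ± 0.33, Pik3ip1 by 1.94 ± 0.22, Ptpn22, a phosphatase of lymphocyte receptor signalling, by 1.51 ± 0.20, Tespa1 by 1.46 ± 0.22 and Dusp2 by 1.43 ± 0.17. Pcdh18 fell by 1.82 ± 0.28, that is 3.53-fold, Id4 by 1.25 ± 0.26 and Ccnb1ip1 by 1.20 ± 0.24. The cytokine gene Il1b fell by 1.21 ± 0.32 and lost its call without vehicle replicate 1 (adjusted p = 0.0512).

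Of 12 mature neutrophil genes in spleen at 1 day, 4 fell and 0 rose, and all 12 fell when adjusted over the list alone (camera adjusted p = 0.00048, adjusted p = 0.843 with an estimated correlation). Mmp9 fell by 1.13 ± 0.30 and Csf3r, the receptor of granulocyte colony-stimulating factor, by 1.07 ± 0.31. Of 7 granulocyte precursor genes 4 fell, 6 when adjusted over the list alone, with the granule protein genes Mpo down by 1.46 ± 0.48 and Elane by 1.24 ± 0.40 (camera adjusted p = 0.0171, adjusted p = 0.845 with an estimated correlation). The neutrophil mean was 10.19 ± 0.72 (SD, n = 4) in vehicle and 9.05 ± 0.13 (n = 4) in baclofen spleens (exact permutation p = 0.0286, the smallest 4 against 4 allow). Without vehicle replicate 1 Mmp9, Csf3r, Mpo and Elane lost their calls (adjusted p = 0.0661, 0.0854, 0.118 and 0.118), and the last 3 lost them without several other libraries in turn. The granulocyte precursor list lost its call without vehicle replicate 2 (adjusted p = 0.0544). Of 11 natural killer and cytotoxic cell genes 5 fell, 1 up and 6 down when adjusted over the list alone, with Ncr1, an activating receptor, down by 0.83 ± 0.13 and the transcription factor gene Tbx21 by 0.68 ± 0.16 (camera adjusted p = 0.0219, adjusted p = 0.845 with an estimated correlation). That call was lost without vehicle replicate 3 (adjusted p = 0.121) or baclofen replicate 3, and with the filter at the 60th percentile (adjusted p = 0.605). Of 17 monocyte and macrophage genes 3 fell by either adjustment, among them Spic, a transcription factor of red pulp macrophages, by 0.77 ± 0.15, and camera did not call the list. Of 16 T cell genes 3 rose, 7 when adjusted over the list alone, among them Il7r, the interleukin 7 receptor, by 1.06 ± 0.19 (camera adjusted p = 6.01e-05, adjusted p = 0.843 with an estimated correlation). Of 8 B cell precursor genes 3 rose, 4 when adjusted over the list alone. Camera called the list (adjusted p = 0.0116, adjusted p = 0.843 with an estimated correlation). That call was lost without vehicle replicate 1 (adjusted p = 0.0818) and with no brightness filter (adjusted p = 0.115).

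Of 14 heat shock genes in spleen at 1 day, 9 fell and 0 rose, and 11 fell when adjusted over the list alone, with Dnaja1 down by 0.61 ± 0.11, Hspa8 by 0.47 ± 0.08, Chordc1 by 0.68 ± 0.12 and Dnajb1 by 0.62 ± 0.13 (camera adjusted p = 1.45e-06, adjusted p = 0.338 with an estimated correlation). The glucocorticoid response list had 9 of 15 members up, 11 up and 1 down when adjusted over the list alone, with Tsc22d3 up by 1.47 ± 0.21 and Per1 by 1.45 ± 0.20 (camera adjusted p = 1.45e-06, adjusted p = 0.338 with an estimated correlation). Foxo1 rose by 0.65 ± 0.15, Scd1, a desaturase of fat synthesis, by 0.86 ± 0.18 and the p53 target gene Bbc3 by 0.77 ± 0.13. The growth factor gene Angpt1 fell by 0.49 ± 0.12. None of 19 mitosis genes and none of 19 DNA replication genes passed, by either adjustment, with medians of -0.64 and -0.47 (camera adjusted p = 0.0141 and 0.0166, adjusted p = 0.847 with an estimated correlation for each). Both calls were lost without vehicle replicate 1 (adjusted p = 0.281 and 0.339), and that of DNA replication with the filter at the 60th percentile (adjusted p = 0.0626). Of 16 megakaryocyte and platelet genes 1 fell by either adjustment (camera adjusted p = 0.000885, adjusted p = 0.845 with an estimated correlation).

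In all, 1697 of 10916 genes passed in spleen at 1 day, 834 up and 863 down (limma). The count was 1005 without vehicle replicate 1, 3050 without vehicle replicate 3, 952 without baclofen replicate 1 and 1002 without baclofen replicate 4. A fit of only these 8 arrays gave 676 and array weights gave 3651.

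After 5 doses, the spleen had fewer genes past the threshold, with the largest rises in Pdk4, Errfi1 and Fam107a. Pdk4 rose 5.44-fold, by 2.44 ± 0.31 (SE, 4 vehicle and 8 baclofen, adjusted p = 0.000192), Errfi1 by 2.17 ± 0.24 and Fam107a by 2.10 ± 0.29. Zbtb16 rose by 1.89 ± 0.29, Fkbp5, a co-chaperone of the glucocorticoid receptor, by 1.62 ± 0.22, Pik3ip1 by 1.58 ± 0.19, Tsc22d3 by 1.43 ± 0.18, Cirbp by 1.40 ± 0.21, Trnp1 by 1.34 ± 0.22 and Per1 by 1.31 ± 0.18. Aplnr, the apelin receptor, fell by 1.04 ± 0.22, and the heat shock gene Hsph1 by 0.79 ± 0.15. Leaving out the 3 spleens with hepatocyte transcripts, an alternative chosen after seeing the data, lowered the count from 484 to 173, with 119 genes in both. These are vehicle replicates 1 and 3 and baclofen replicate 5. The loss of vehicle samples and the loss of hepatocyte transcripts cannot be told apart as the source of this fall. Without them Ddit4, up by 1.33 ± 0.27 in the full data, had an adjusted p of 0.0653, Aplnr 0.123 and Hsph1 0.0819.

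Of 13 clock genes in spleen at 5 days, 6 rose, 8 up and 1 down when adjusted over the list alone, with Hlf up by 0.64 ± 0.11 and Tef by 0.63 ± 0.13 (camera adjusted p = 2.34e-05, adjusted p = 0.536 with an estimated correlation). The glucocorticoid response list had 9 of 15 members up, 10 when adjusted over the list alone, with Klf9 up by 1.25 ± 0.13 (camera adjusted p = 3.91e-09, adjusted p = 0.171 with an estimated correlation). Of 14 heat shock genes 8 fell, 11 when adjusted over the list alone, Dnaja1 by 0.48 ± 0.09 (camera adjusted p = 6.85e-07, adjusted p = 0.338 with an estimated correlation). The list's mean was 10.27 ± 0.19 (SD, n = 4) in vehicle and 9.91 ± 0.10 (n = 8) in baclofen spleens (exact permutation p = 0.00404). Without the 3 spleens with hepatocyte transcripts Dnaja1 had an adjusted p of 0.104, Hlf 0.0824 and Il7r 0.055. Tef lost its call without vehicle replicate 2 (adjusted p = 0.0527). Of 19 endothelial genes 5 rose, 10 when adjusted over the list alone, Sox18 by 0.45 ± 0.10 (camera adjusted p = 7.85e-07, adjusted p = 0.695 with an estimated correlation). Sox18 lost its call without vehicle replicate 2 (adjusted p = 0.0849). Of 5 adipocyte genes 2 rose, 3 when adjusted over the list alone, the fatty acid binding protein gene Fabp4 by 2.30 ± 0.55 (camera adjusted p = 0.0281, adjusted p = 0.536 with an estimated correlation). Fabp4 lost its call without vehicle replicate 1, 2 or 4 (adjusted p = 0.0695, 0.075 and 0.052), and its list lost it without vehicle replicate 1 (adjusted p = 0.0731) or 4. The list also lost its call in 4 of 10 other settings, among them that without the spleens with hepatocyte transcripts. Id1 rose by 0.69 ± 0.12, Il7r by 1.07 ± 0.16 and Gata2 by 0.41 ± 0.07, and Btg2 fell by 0.34 ± 0.07.

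None of 19 mitosis genes passed in spleen at 5 days over all genes, and 19 fell when adjusted over the list alone, with a median of -0.99 (camera adjusted p = 7.23e-08, adjusted p = 0.843 with an estimated correlation). Of 23 erythroid genes 0 passed by either adjustment, with a median of -0.80 (camera adjusted p = 9.92e-05, adjusted p = 0.845 with an estimated correlation). The erythroid call was lost without vehicle replicate 2 (adjusted p = 0.0568). The erythroid mean was 10.66 ± 0.98 (SD, n = 4) in vehicle and 9.83 ± 0.78 (n = 8) in baclofen spleens, a difference within the spread of the groups (exact permutation p = 0.139). For mitosis the means were 9.55 ± 0.58 and 8.61 ± 0.59 (exact permutation p = 0.0263). Of 13 unfolded protein response genes 2 fell, 5 when adjusted over the list alone (camera adjusted p = 0.00154, adjusted p = 0.826 with an estimated correlation), and the call was lost without the spleens with hepatocyte transcripts (adjusted p = 0.099). The RNA quality sign was 0.34 ± 0.02 (SD, n = 4) in vehicle and 0.39 ± 0.10 (n = 8) in baclofen spleens at 5 days.

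**Figure D4:**
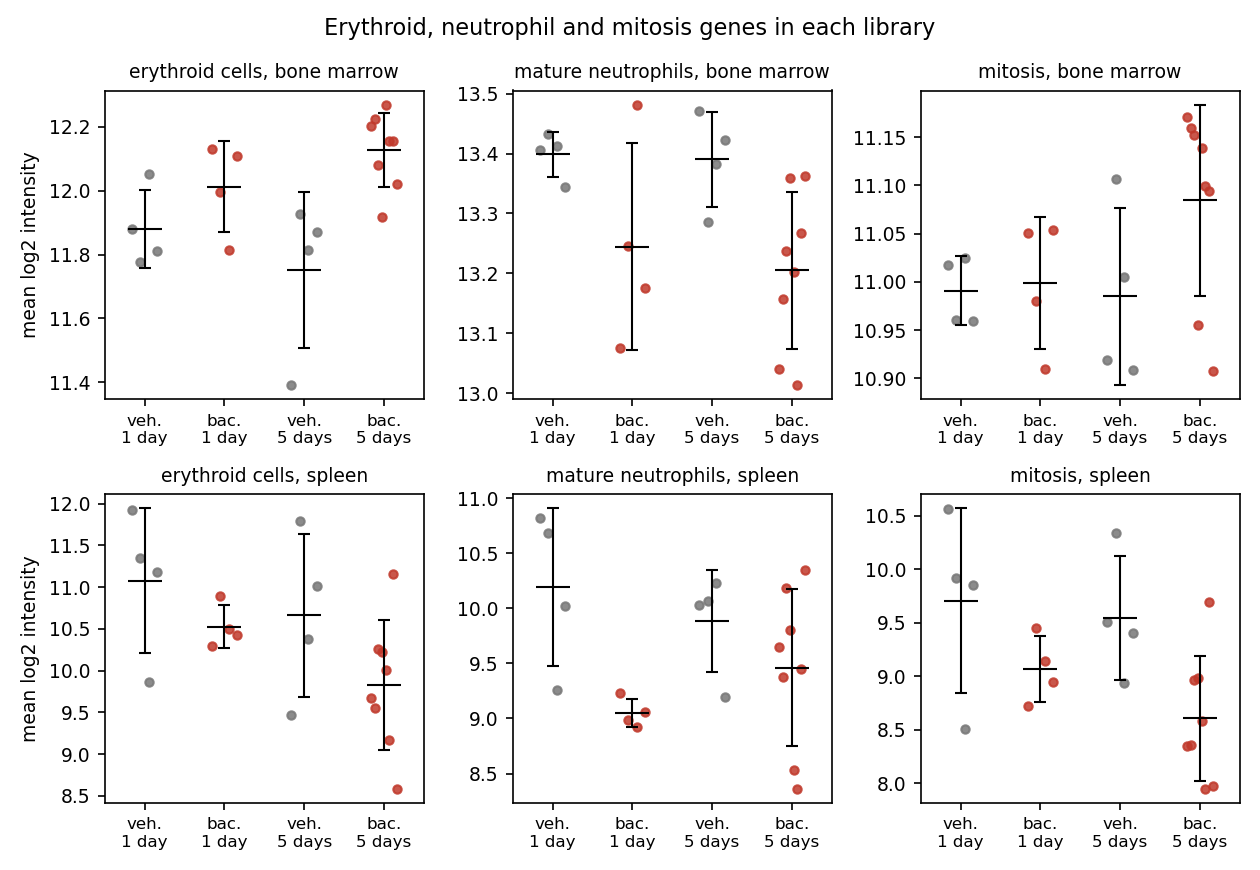
Mean log2 intensity of erythroid, mature neutrophil and mitosis genes in each bone marrow and spleen library, with black bars for the group mean ± SD. Erythroid genes were higher under baclofen in marrow at 5 days, and the erythroid mean of the 4 vehicle spleens at 5 days ranged from 9.47 to 11.79.

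In all, 484 of 10916 genes passed in spleen at 5 days, 333 up and 151 down (limma). The count was 275 without vehicle replicate 1, 136 without vehicle replicate 2, 288, 322 and 291 without baclofen replicates 1, 5 and 6, 758 without baclofen replicate 7 and 267 with the RNA quality sign as a covariate, and array weights gave 744. At both times 192 genes rose, against 25.4 expected, 103 fell, against 11.9 expected, and 0 moved in opposite directions (r = 0.68 and rho = 0.69 across genes). The change of the effect from 1 to 5 days passed for 0 genes by limma, with 858 at an unadjusted p under 0.05.

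Vehicle at 5 days against vehicle at 1 day served as a background of time and repeated dosing without the drug. By limma 0 genes passed in liver, bone marrow and spleen, with 779, 510 and 378 genes at an unadjusted p under 0.05. In liver 2 passed without vehicle 1 day replicate 2 and 3 without vehicle 5 day replicate 4, and in bone marrow 523 passed with array weights. The baclofen comparisons have 1363 and 2910 such genes in liver, 2629 and 2884 in bone marrow and 3498 and 2822 in spleen. Camera called 4 of 37 lists in liver, 6 of 42 in bone marrow and 14 of 41 in spleen, of which 0 held with an estimated correlation and 0 were called by fry. Under baclofen camera called 8 lists up and 2 down in liver at 1 day, and 10 and 2 at 5 days. In bone marrow these were 6 and 1, then 6 and 7, and in spleen 4 and 8, then 7 and 7. In spleen at both times and in bone marrow at 1 day, camera calls were thus about as many as without the drug. A camera call there does not by itself tell a baclofen effect from spread between samples. Some of the lists called in vehicle were also called under baclofen. Acute phase genes were higher at 5 days in liver (18 of 18 positive, median 0.11, adjusted p = 0.0319), and erythroid genes were lower in bone marrow (22 of 23 negative, median -0.13, adjusted p = 1.78e-05) and in spleen (23 of 23 negative, median -0.45, adjusted p = 0.00645). Megakaryocyte and platelet genes were lower in spleen (16 of 16 negative, median -0.49, adjusted p = 8.97e-17). With an estimated correlation the adjusted p was 0.957 for the first 3 and 0.906 for the last. Hepatocyte genes in spleen had a median difference of 2.10 (camera adjusted p = 0.000121, adjusted p = 0.906 with an estimated correlation, fry adjusted p = 0.287), and 2 of the 4 vehicle spleens at 5 days are among the libraries with hepatocyte transcripts.

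Genes that rose in all 6 baclofen comparisons numbered 8. They are Ddit4, Dusp1, Per1, Sgk1, Txnip, an inhibitor of thioredoxin, Mlxip, a glucose-sensing transcription factor, Pnpla2, a triglyceride lipase, and Sgms1, a sphingomyelin synthase. Their log2 fold changes ranged from 1.33 to 3.43 for Ddit4, 1.31 to 2.22 for Per1, 0.92 to 2.10 for Dusp1, 0.33 to 1.89 for Sgk1 and 0.42 to 1.14 for Txnip. Cirbp passed in 5 and had 0.75 ± 0.24 in liver at 5 days (adjusted p = 0.0546). At 1 day 16 genes rose in all 3 tissues, against 0.298 expected if the calls were independent, and 11 fell, against 0.342 expected. At 5 days 22 rose in all 3 tissues, against 0.712 expected, and 1 fell, against 0.306 expected. Between bone marrow and spleen at 1 day 132 genes rose in both and 146 fell in both, against 24 and 36.1 expected, and 2 moved in opposite directions. At 5 days 74 rose in both, 20 fell in both and 9 moved in opposite directions, and the fold changes correlated with r = 0.026 across genes, against 0.31 at 1 day. The independence behind each expected number does not hold strictly. Libraries of 1 number resembled each other between tissues and may come from 1 animal. Calls at the 2 times of a tissue share 1 estimate of spread per gene. Genes are not independent of each other either.

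**Figure D5:**
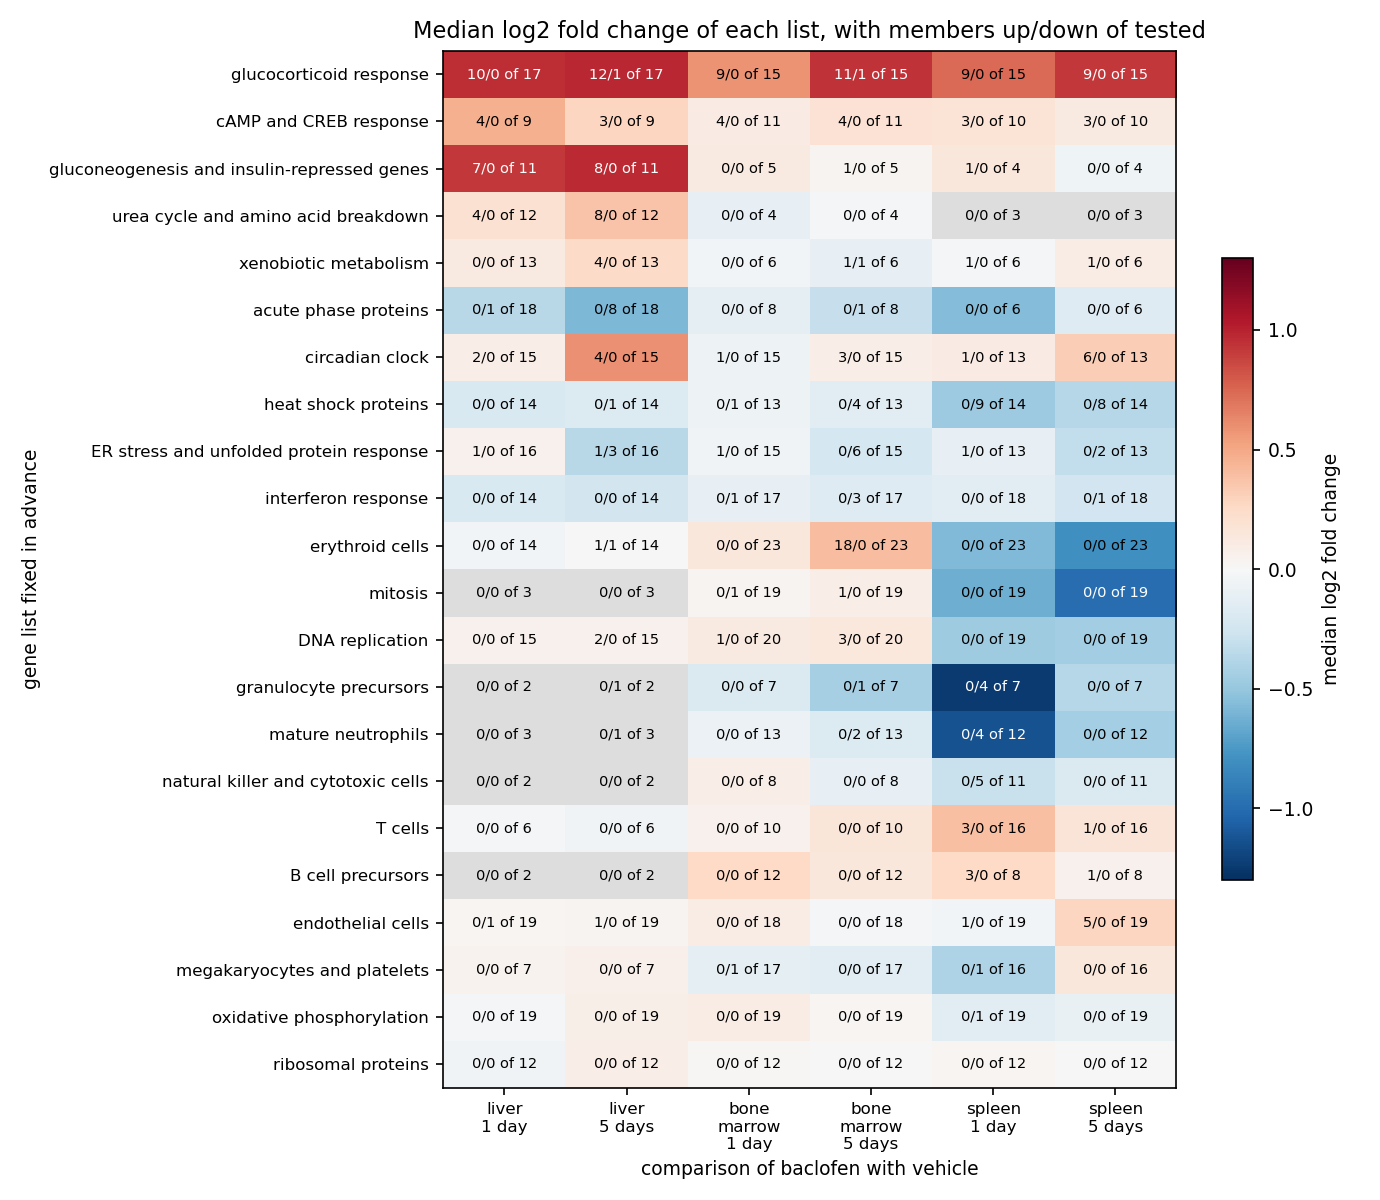
Median log2 fold change (color) of 22 gene lists in the 6 comparisons of baclofen with vehicle, with the number of members up and down of those tested written in each field, and gray for under 4 tested members. Glucocorticoid response genes had 9 to 12 of 15 or 17 members up, and 1 member down in liver and in bone marrow at 5 days. The call of this list held with an estimated correlation in liver at each time and was lost in the other 4 comparisons.

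The baclofen effect differed between tissues. Between liver and bone marrow at 1 day 213 genes differed, 144 with a higher and 69 with a lower effect in liver. The difference, liver minus bone marrow, was 2.80 ± 0.33 for the transcription factor gene Cebpd (adjusted p = 5.63e-08), 2.23 ± 0.19 for the amino acid transporter gene Slc38a2, -3.66 ± 0.55 for Arrdc3 and -2.41 ± 0.32 for Id2. Between liver and spleen at 1 day 607 genes differed, 338 higher and 269 lower in liver, with 3.73 ± 0.74 for Mt2, 3.35 ± 0.57 for Noct, -3.82 ± 0.55 for Arrdc3 and -2.40 ± 0.38 for Phlda1. That count was 387 without liver vehicle replicate 2, 338 without spleen vehicle replicate 1 and 1235 without spleen vehicle replicate 3. Between bone marrow and spleen at 1 day 195 genes differed, 95 higher and 100 lower in marrow, with 1.75 ± 0.43 for Ccn1, 0.93 ± 0.17 for Sap30, -1.48 ± 0.20 for Ifit1bl2 and -1.23 ± 0.19 for Cd69, an early activation marker of lymphocytes. Ccn1 lost its call without spleen vehicle replicate 1 (adjusted p = 0.0824) and without 7 other libraries in turn. The count was 26 without spleen vehicle replicate 1, 1722 without spleen vehicle replicate 3 and 4 in a fit of only the groups compared.

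At 5 days 731 genes differed between liver and bone marrow, 354 higher and 377 lower in liver, with 1.92 ± 0.16 for Slc38a2, 1.94 ± 0.32 for Usp2, -3.62 ± 0.89 for Lcn2 and -2.004 ± 0.293 for Id3. Between liver and spleen 1086 differed, 558 higher and 528 lower in liver, with 3.06 ± 0.47 for Noct, 1.91 ± 0.20 for Coq10b, a mitochondrial coenzyme Q protein gene, -2.25 ± 0.26 for Id2 and -2.07 ± 0.52 for Fabp4. That count was 673 without liver vehicle replicate 3 and 603 without spleen vehicle replicate 2. Between bone marrow and spleen 458 differed, 307 higher and 151 lower in marrow, with 1.89 ± 0.50 for Trim10, an erythroid gene, 2.13 ± 0.49 for Tmcc2, 2.05 ± 0.52 for Ypel4, -1.31 ± 0.18 for Neto2 and -1.78 ± 0.50 for Pdk4. Without spleen vehicle replicate 2 Trim10, Tmcc2 and Ypel4 lost their calls (adjusted p = 0.161, 0.083 and 0.148), and Pdk4 lost its call without spleen vehicle replicate 1 (adjusted p = 0.0704). Of 23 erythroid genes 5 and of 19 mitosis genes 7 had a higher effect in marrow, with medians of 1.22 and 1.06 (camera adjusted p = 2.64e-11 and 8.71e-11, adjusted p = 0.906 with an estimated correlation for each). The count was 146 without marrow vehicle replicate 1, 80, 725 and 866 without spleen vehicle replicates 2, 1 and 3, 301 and 1180 without spleen baclofen replicates 6 and 7, 690 without marrow baclofen replicate 8, and 1160 without the 4 libraries with transcripts of another tissue.

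The receptor subunit gene Gabbr1 passed in no comparison, with log2 fold changes from -0.09 in bone marrow at 1 day to 0.19 in spleen at 5 days. Of the other genes of GABA-B signalling, the potassium channel gene Kcnj5 fell by 0.63 ± 0.19 in bone marrow at 1 day, and it lost its call without vehicle replicate 4 (adjusted p = 0.149) and without 6 other libraries in turn. Over the 6 baclofen comparisons camera made 68 list calls. With an estimated correlation 4 held, the glucocorticoid response and the gluconeogenesis lists in liver at each time. By fry, which compares a list with no other genes, 28 lists were called. They include glucocorticoid response genes in each of the 6 comparisons and heat shock genes in spleen at both times.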

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

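The tests of hepatocyte transcripts, of erythroid and mitosis genes and of the liver labels were chosen after the results they concern were seen, while the counts over other splits follow a fixed procedure whose bounds were written down after the results.

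In each group of 4 or 8 libraries, the mean of each list and the values of the shared genes were searched for a library whose gap to the nearest other library was large against the range of its group. Chance gives about 1 in 20 groups, and 17 of 311 groups, 5.47%, held such a library, near the number chance gives. Values are mean log2 intensities, with the range of the other libraries of the group in brackets. In liver, fasting and PPAR-alpha response genes stood at 9.975 in baclofen 1 day replicate 1 (9.37 to 9.47), ribosomal protein genes at 12.131 (12.01 to 12.02) and Per1 at 9.051 (8.28 to 8.39) in baclofen 1 day replicate 4, Txnip at 9.143 in vehicle 5 day replicate 4 (8.34 to 8.42), and acute phase genes at 11.885 in baclofen 5 day replicate 8 (10.44 to 11.08). In bone marrow at 1 day, cAMP and CREB response genes stood at 7.967 (8.04 to 8.05) and monocyte and macrophage genes at 9.649 (10.06 to 10.12) in vehicle replicate 1, acute phase genes at 10.08 in vehicle replicate 2 (9.73 to 9.77), skeletal muscle genes at 6.744 in vehicle replicate 4 (7.42 to 7.52) and Cirbp at 9.529 in baclofen replicate 3 (10.13 to 10.20). At 5 days cAMP and CREB response genes stood at 8.02 in marrow vehicle replicate 4 (7.89 to 7.90). In spleen, megakaryocyte and platelet genes stood at 8.72 in vehicle 1 day replicate 3 (9.41 to 9.51), Pnpla2 at 8.667 in baclofen 1 day replicate 3 (8.83 to 8.86) and at 9.104 in baclofen 5 day replicate 6 (8.78 to 8.90), and unfolded protein response genes at 11.039 in vehicle 5 day replicate 1 (10.15 to 10.23). Interferon response genes stood at 9.018 in spleen baclofen 5 day replicate 2 (8.09 to 8.32), and hepatocyte genes at 9.054 in spleen baclofen 5 day replicate 5 (4.78 to 5.56).

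A difference between groups was found by its own test for 13 results. The change from 1 to 5 days passed for 2 genes in liver. The baclofen effect differed at 1 day for 213 genes between liver and bone marrow, 607 between liver and spleen and 195 between bone marrow and spleen, and at 5 days for 731, 1086 and 458 genes. For 6 lists camera and fry called a difference between tissues that was lost with an estimated correlation (adjusted p = 0.906 for each). The median differences were 0.11 for p53 targets between liver and bone marrow at 1 day, and 0.246 for hypoxia response, 0.247 for immediate early and 0.449 for xenobiotic metabolism genes between liver and bone marrow at 5 days. Between liver and spleen at 5 days they were -0.63 for adipocyte and 0.557 for gluconeogenesis and insulin-repressed genes.

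Each count was compared with other splits of the same libraries into groups of the same sizes. For the 6 baclofen comparisons few splits reached the real count, which argues against chance without excluding it. In liver at 1 day 1 of 35 splits gave as many genes (the real one, 291, highest other 96), and at 5 days 1 of 100 (1159, highest other 420). In bone marrow these were 1 of 35 (803, highest other 158) and 2 of 100 (1100, highest other 1187). In spleen they were 1 of 35 (1697, highest other 623) and 2 of 100 (484, highest other 494). At 5 days the highest other split left 10 of 12 libraries of each tissue under their real treatment. At 1 day it left 1 of 7 livers, 2 of 8 marrows and 6 of 8 spleens, so in liver and marrow it largely turned the effect around. These highest counts therefore carry part of the baclofen effect. The median over the other splits was 0 in each of the 6 comparisons. For the change of the effect in liver 2 of 100 splits gave as many genes (real count 2, highest other 3). These splits take away the baclofen effect at each time, so they cannot decide whether a change of that effect is chance. The count rests on 2 genes. It was 0 without any 1 of 10 of the 19 libraries, with the 60th percentile filter and with the mean of probe sets. Where the real count is 0, each split reaches it and the comparison says nothing about chance. This holds for that change in bone marrow (100 of 100, 0, highest other 1) and in spleen (100 of 100, 0, highest other 1752), and for vehicle over time in liver (35 of 35, 0, highest other 23), bone marrow (35 of 35, 0, highest other 224) and spleen (35 of 35, 0, highest other 2634). Splits of vehicle spleens with 2634 genes and of vehicle marrows with 224 point to a structure of the vehicle samples other than time. The split with 1752 genes left 2 of 8 spleens of 1 day and 10 of 12 of 5 days under their real treatment, so it largely turned the baclofen effect at 1 day around, and a structure of the samples was not told from this. The splits for differences between tissues reassign the libraries of each tissue separately and treat them as independent, which does not hold if libraries of 1 number come from 1 animal. These splits also take away the baclofen effect within each tissue. They ask about no effect in either tissue and not about an equal effect in both. So they cannot decide whether a difference between tissues is chance. At 1 day 2 of 100 splits reached the real count between liver and bone marrow (213, highest other 425). The same share did so between liver and spleen (607, highest other 1048). At 5 days 1 of 100 did so between liver and bone marrow (731, highest other 516). It was also 1 of 100 between liver and spleen (1086, highest other 508) and between bone marrow and spleen (458, highest other 411). Between bone marrow and spleen at 1 day 7 of 100 did so (195, highest other 714). That split has several times the real count and left 4 of 8 marrows and 6 of 8 spleens under their real treatment, so the baclofen effect in spleen can make up part of its count, and whether a structure of the samples adds to it was not tested.

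Hepatocyte transcripts stood above the other spleens in 3 spleen libraries of 5 days, vehicle replicates 1 and 3 and baclofen replicate 5. A liver library under a spleen label is argued against, since the correlation with other spleens exceeded that with livers by at least 0.2732 in each of the 3. RNA or cells of liver are a candidate source in vehicle replicate 3 and baclofen replicate 5, where 98.26 and 97.39 percent of 115 genes abundant in liver and dim in spleen lay above all 8 spleens of 1 day (11.1 percent by chance), with Alb at 12.3 and 11.8 against at most 5.44 on the log2 scale. For vehicle replicate 1, with 75.65 percent and Alb at 8.70, this source cannot be told apart from other sources of weak liver signal, since its share of genes and its signal were lower. Of the 12 hepatocyte genes 4 pass the brightness filter in spleen, and no biological explanation was tested.

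Erythroid and mitosis genes had lower means in baclofen than in vehicle spleens, by list medians of -0.80 and -0.99 at 5 days. RNA quality as the whole cause is argued against. With the difference between 3' and 5' control probe sets as a covariate the medians were -0.633 and -0.855. Without the libraries with hepatocyte transcripts the camera adjusted p was 6.73e-14 for erythroid and 6.2e-11 for mitosis genes. That run leaves out vehicle replicates 1 and 3, so few vehicle spleens of 5 days remain. The calls of both lists in the full data are lost with an estimated correlation. In those 3 libraries the 115 genes abundant in liver stood only slightly above the mean of the 1-day spleens. The median rise was 0.116 percent of the distance to their liver intensity in vehicle replicate 1. It was 0.86 percent in vehicle replicate 3 and 0.768 percent in baclofen replicate 5. So small a share, found in more vehicle than baclofen libraries, argues against liver RNA as the whole cause of the lower medians. Spread between spleens may explain the erythroid difference (both times together, -0.69, 2-sided permutation p = 0.0546, 12 baclofen and 8 vehicle libraries). For mitosis the same test gave -0.79 (permutation p = 0.0123, adjusted p = 0.0246), which argues against spread alone without excluding it. The 2 differences are near in size, and whether they differ from each other or move together was not tested. Within vehicle the erythroid mean ranged from 9.47 to 11.9, so the share of red cell precursors in each spleen piece stays open. A lower share of dividing cells under baclofen stays open as a hypothesis.

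The 1-day livers carry 2 sets of treatment labels. Under the source field the 1-day effect correlated across genes with the 5-day effect at r = -0.329, against 0.59 under the titles, where genes are not independent replicates. The 32 genes that rose in bone marrow and spleen at both times had a median of -0.16 in liver under the source field, with 1 of them positive, and of 0.248 under the titles, with 27 positive. Both values argue against the source field as the right set. A single wrong title among the 7 livers stays open, and no biological explanation was tested.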

How the results depend on the processing

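Alternatives were fixed before the data were examined, except the one without 4 libraries holding another tissue's transcripts, chosen after seeing the data. The named genes were followed through the alternatives, except Txnip, Mlxip, Sgms1 and Pnpla2. All genes followed that passed the threshold kept their direction under each alternative except the source field labels. Leaving out any 1 library kept the call of 28 of 38 genes followed in liver at 1 day, 31 of 42 at 5 days, 18 of 27 in bone marrow at 1 day, 25 of 40 at 5 days, 29 of 39 in spleen at 1 day and 24 of 34 at 5 days. In the same order, the number that kept it through all the alternatives other than the source field, stricter thresholds and probe sets apart was 23 of 38, 23 of 42, 17 of 27, 2 of 40, 30 of 39 and 0 of 34. The replicate block alone left 2 genes each in marrow and spleen at 5 days. That block makes no use of 5-day baclofen libraries whose number has no vehicle library. A dim gene near the array's background shows a compressed change, so small fold changes of genes just above the brightness filter set a limit. Stricter thresholds give fewer genes by construction, probe sets apart add tests, and fits of fewer groups have fewer samples. For the other changes below the cause was not tested.

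Counts are given for liver, bone marrow and spleen at 1 and 5 days, then for the differences liver to marrow, liver to spleen and marrow to spleen. With adjusted p under 0.01 the counts were 125 and 382, 225 and 173, 601 and 117, then 109, 201 and 26 at 1 day and 315, 396 and 113 at 5 days, and 0 for the change in liver. With at least 1.5-fold change they were 171 and 287, 97 and 72, 285 and 101, then 266 (liver to spleen) and 101 (marrow to spleen) at 1 day and 248, 339 and 249 at 5 days. With probe sets apart they were 750 and 2143 in liver, 1431 in marrow at 1 day, 3605 and 1021 in spleen, 4 for the change in liver, 391 and 1167 for liver to marrow and liver to spleen at 1 day, and 1220, 2131 and 822 at 5 days. With array weights they were 518 and 720, 2416 and 4404, 3651 and 744, 45 and 33 for the change in marrow and spleen, 523 for vehicle over time in marrow, 554, 1439 and 2333 at 1 day, and 1386 (liver to marrow) and 1695 (marrow to spleen) at 5 days. A fit of only the groups compared gave 269 in marrow and 676 in spleen at 1 day, 140, 195 and 4 for the differences at 1 day, and 639 (liver to spleen) and 243 (marrow to spleen) at 5 days. The RNA quality covariate gave 739 in liver and 267 in spleen at 5 days. Without the libraries holding another tissue's transcripts there were 1412 in marrow at 1 day (770 shared with the 803), 173 in spleen at 5 days, and 383 and 1160 for marrow to spleen at 1 and 5 days. The filter at the 60th percentile gave 0 for the change in liver and 121 for liver to marrow at 1 day, the mean of probe sets gave 0 for that change, centring gave 1 for vehicle over time in liver, and quantile normalization gave 497 and 710 for marrow to spleen. Of the 68 list calls 4 held with an estimated correlation and 28 by fry.

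With the replicate number as a replicate block the counts were 139 and 231 in liver, 413 and 2 in marrow, 871 and 2 in spleen, 0 for the change in liver, and 363 and 751 for marrow to spleen. Within a tissue only numbers with both a vehicle and a baclofen library bear on the blocked effect. That left 4 such pairs at the later time in each tissue, and the other baclofen libraries dropped out. The loss of samples and the block cannot be told apart as the source of the lower counts there. Within a tissue, vehicle and baclofen libraries of 1 number correlated with r from -0.46 to 0.27 after removal of group means, so these do not appear paired. For marrow to spleen the block instead joins libraries of 1 group and number across tissues. Those resembled each other (mean r = 0.0986, 1-sided permutation p = 0.0047), and the main counts of differences between tissues leave this out.

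Leaving out 1 library at a time gave 136 to 306 and 584 to 1545 in liver, 303 to 1412 and 244 to 1674 in marrow, 952 to 3050 and 136 to 758 in spleen, 0 to 6 for the change in liver, 0 to 1 in marrow and 0 to 0 in spleen, 0 to 3 for vehicle over time in liver and 0 in marrow and spleen. For the differences it gave 146 to 272, 338 to 1235 and 26 to 1722 at 1 day and 496 to 889, 603 to 1373 and 80 to 1180 at 5 days.

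Under the source field labels the counts were 0 in liver at 1 day, 72 for the change and 187 for vehicle over time. The log2 fold changes that reversed in liver at 1 day were then Igfbp1 -2.456, Ddit4 -1.352, Mt2 -1.156, Snhg3 -1.259, Ppp1r3g -1.331, Mfsd2a -0.452, Plin4 -0.781, Fam107a -0.745, Noct -0.165, Trp53inp1 -0.831, Phlda1 0.251, Hhex 0.25, Arrdc3 0.702, Osgin1 0.641, Foxq1 0.011, Foxa1 0.548, Fzd7 0.117, Id2 0.633, Angptl8 1.515, Id3 0.634, Tat -0.465, Sgk1 -0.574, Dusp1 -0.634, Ppargc1a -0.896, Per1 -0.304, Foxo1 -0.398, G6pc -0.457, Ass1 -0.39, Gpt2 -0.229, Got1 -0.251, Cirbp -1.061, Herpud1 -0.071, Ciart -0.561, Slc2a1 -0.457, Sox18 0.383, Socs3 0.091, Nfkbia -0.123 and Btg2 -0.757. The list medians that reversed were -0.191 for cAMP and CREB response, 0.00722 for circadian clock, -0.36 for glucocorticoid response, -0.325 for gluconeogenesis and insulin-repressed genes, -0.00774 for hypoxia response, -0.0559 for interferon response, -0.0602 for p53 targets and -0.0918 for urea cycle and amino acid breakdown, where the clock and interferon lists reversed in camera's direction and not in the sign of the median. The differences that reversed were Snhg3 -1.723, Slc38a2 -0.576, Phlda1 0.521, Hhex 0.533 and Osgin1 0.959 for liver to marrow and Mt2 -0.685, Snhg3 -1.383, Phlda1 0.684, Hhex 0.562, Osgin1 0.669 and Id2 0.127 for liver to spleen.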

Other observations

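The tests in this part were chosen after the results were seen, except the camera tests of the fixed lists and the counts of their members.

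The difference between clock output genes and the genes of the opposite phase, Arntl, Clock and Npas2 (2 of them bright enough in each tissue), was higher under baclofen by 0.255 in liver, 0.087 in bone marrow and 0.217 in spleen at 1 day, and by 1.477, 0.38 and 0.755 at 5 days. The 2-sided exact permutation p was 0.657, 0.4 and 0.114 at 1 day and 0.0182, 0.0667 and 0.00202 at 5 days, the last being the smallest that 4 against 8 allow. Adjusted over the 6 tests, spleen at 5 days passed (adjusted p = 0.0121), and liver at 5 days did not (adjusted p = 0.0546). A shift of clock phase may take part in the response of spleen and possibly liver, while in the other 4 groups it cannot be told apart from no shift with the spread present. The output genes include Hlf, Tef, Ciart and Nr1d2, already called at 5 days, so this difference does not stand apart from those calls. Of the 4 vehicle spleens at 5 days 2 hold hepatocyte transcripts. The labels do not give the hour of killing, so a difference in hour between groups stays open. The clock list did not pass in the test of the change from 1 to 5 days (camera adjusted p = 0.619 in liver, 0.226 in bone marrow and 0.0506 in spleen, 0 members passed), so no growth of the shift with repeated dosing is claimed.

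Libraries of the same group and number in 2 tissues resembled each other more than libraries of other numbers, with a mean r after removal of group means of 0.0784 between liver and bone marrow (1-sided permutation p = 1e-04, the smallest the permutations can give), 0.0701 between liver and spleen (1-sided permutation p = 3e-04) and 0.0986 between bone marrow and spleen (1-sided permutation p = 0.0047). Over the 8 numbers of the 5-day baclofen group, Cirbp correlated between bone marrow and spleen with r = 0.96 (2-sided exact p = 0.00112, rho = 0.952, exact p = 0.00114, r = 0.94 without the 2 numbers farthest from the median, adjusted p = 0.00672 over 6 relations). For liver and bone marrow r was 0.409 (exact p = 0.313, rho = 0.333, exact p = 0.428, r = 0.233 without 2, adjusted p = 0.313), and for liver and spleen 0.52 (exact p = 0.182, rho = 0.5, exact p = 0.216, r = 0.235 without 2, adjusted p = 0.218). The glucocorticoid response mean gave r = 0.558 for liver and bone marrow (exact p = 0.148, rho = 0.69, exact p = 0.0694, r = 0.778 without 2, adjusted p = 0.218), 0.752 for liver and spleen (exact p = 0.0307, rho = 0.833, exact p = 0.0154, r = 0.527 without 2, adjusted p = 0.0921) and 0.688 for bone marrow and spleen (exact p = 0.0609, rho = 0.595, exact p = 0.132, r = 0.733 without 2, adjusted p = 0.122). Libraries of 1 number may come from 1 animal, in which Cirbp would then differ as a whole, but a shared day of processing was not tested.

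Cirbp is induced by cold and heat shock genes by heat, so a fall of body temperature is a candidate explanation where Cirbp was higher and heat shock genes lower. Heat shock genes past the threshold and lower were 9 of 14 at 1 day and 8 of 14 at 5 days in spleen, 1 of 13 and 4 of 13 in bone marrow, and 0 of 14 and 1 of 14 in liver. Camera called the list in spleen at both times and in bone marrow at 5 days, and not in the other 3 comparisons. None of these calls held with an estimated correlation. The counts of members do not rank the times, since the list's change from 1 to 5 days passed in no tissue (camera adjusted p = 0.898 in liver, 0.0509 in bone marrow and 0.217 in spleen). Counts past a threshold do not by themselves rank tissues either. A fall of body temperature would make Cirbp and heat shock genes move in opposite directions from library to library. After removal of group means, r of Cirbp with the heat shock mean was -0.459 in liver (n = 19, 2-sided permutation p = 0.188, rho = -0.289, permutation p = 0.276, r = 0.0403 without the 2 libraries farthest from the median, adjusted p = 0.442 over 3 relations). It was -0.135 in bone marrow (n = 20, permutation p = 0.508, rho = -0.152, permutation p = 0.528, r = -0.289 without 2, adjusted p = 0.508) and -0.285 in spleen (n = 20, permutation p = 0.295, rho = -0.223, permutation p = 0.39, r = -0.282 without 2, adjusted p = 0.442). With this spread the explanation cannot be told apart from separate effects on the 2, and the labels give no temperature.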
